A study of Homo sapiens with 32 samples.

How the data were processed

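The 4 libraries described here are m6A immunoprecipitations of chromatin-associated, ribosome-depleted RNA of A375 cells, 2 with a control hairpin RNA and 2 with a hairpin RNA against METTL3. Per the labels' protocols, a methylated RNA spike-in was added before fragmentation, enrichment used a commercial m6A antibody kit, and libraries were made with a stranded total RNA kit. The submitters' processing notes name Trim Galore 0.6.6, Bowtie2 2.4.2, HISAT2 2.1.0, SAMtools and MACS2 2.2.7.1, and the build hg38, without roles or order. How the spike-in or the input libraries entered the peak calls is not given in the sources used here.

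The deposited files are peak lists, one per library, so peaks were called per library and not on pooled samples. Per the peak names in the deposited files, peaks were called separately for each strand; peaks of 1 strand do not overlap within a list and are at least 150 bp wide. The peak names of the knockdown lists use a knockout prefix where the labels say knockdown. The fold enrichment, a ratio, is the deposited value of the peak caller at the summit of each peak. The p-value and q-value of each peak were deposited as −log10 values, and the smallest −log10 q in the lists was 2.00. The deposited score repeats the −log10 q and was not used. Folds were used to rank or describe peaks within a list and, with 1 cut common to all lists, to filter them. Counts after this filter also depend on the fold scale of each list. Unless the spike-in was used to scale them, which is not stated, folds are relative to the other RNA of the same library. Without such scaling, a drop of m6A that is equal at all sites would leave little trace in these lists. A lower RNA level of a gene can remove its peaks without any change in methylation.

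Peaks of the 4 lists were merged to loci where they shared at least 1 bp on the same strand. A locus was control-only (also called lost) with a peak in both control lists and neither knockdown list, and knockdown-only (gained) in the reverse case. Loci were placed by the summit of their strongest peak in gene spans of a RefSeq table (39933 genes, GRCh38.p14, the same build as hg38). That table has neither exons nor strands. The regions planned by transcript part (UTR, coding, stop codon, intron) were therefore replaced by the first 500 bp of a gene, its last 2000 bp and its interior. A locus in both windows counted as gene end, so all loci of genes shorter than 2000 bp are gene ends. A gene took the strand that held at least 80% of at least 3 loci lying in it alone, which gave a strand to 6070 genes. Inferred strands rest on the peaks alone. The other genes accepted loci of either strand, with start and end read from the strand of the locus. In these genes, loci of the opposite strand count as the gene's own, and start and end can be swapped. Loci compatible with more than 1 gene, outside genes or on the opposite strand of a gene were kept apart, and 81.6% of loci were placed in a single gene; overlapping genes such as MALAT1 and its antisense partner could not be separated. Summits anywhere in the gene counted, introns included.

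A gene was measured with at least 1 locus in both control lists, and lost if all of these were control-only; gain was defined the same way from the knockdown lists and was added after the data were seen, as was the test of direction by list. A binomial test per gene, also added then, is left out of the text, because it takes the loci of a gene as independent and they moved together. The share lost or gained was compared by two-sided Fisher's exact tests over loci (regions) or genes (lists), with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Of 17 gene lists fixed before the data were examined, 13 had at least 5 measured genes and were tested. Library values were compared by exact permutation tests of 2 against 2, which cannot go below p = 0.333. Folds of moved and shared loci were compared within each list by permutation (100000 resamples), and directions of gene lists by 10000 draws of genes with similar numbers of moved loci. Shares have 95% Wilson intervals, which cover counting error only; the read depth is unknown.

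Centromere annotation and genome sequence were not used here, so centromeric intervals were replaced by the 27 gene-free intervals of at least 2 Mb, with 5 Mb on either side as neighbouring sequence. The planned search for the m6A sequence motif and the count of summits in masked repeats need the sequence and were not run. Named genes followed a rule fixed before the data were examined: METTL3 first, then the 12 genes with the highest-ranked control-only locus, 8 with a knockdown-only locus and 6 with a locus in all 4 lists, by the lower fold percentile of the lists that hold the peak, then for each list up to 2 lost and 2 kept members, and up to 5 loci in and 5 near gene-free intervals. Genes with uncharacterized symbols were left out of the ranked parts. Other members of the lists are named as examples, chosen after their values were seen.

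Alternatives covered the overlap rule (reciprocal 50%; merging within 100 bp), thresholds (−log10 q of at least 5; fold of at least 4), lists cut to equal length, each library left out, 10 (loci) or 5 (genes) classes of peak strength by the Cochran-Mantel-Haenszel odds ratio, with an exact conditional test that was put in place of the planned chi-square approximation after the result of the approximation was seen, main chromosomes only, and neighbouring sequence of 2 Mb. Added after the data were seen were a gene end of 1000 bp, a −log10 q of at least 20, and 1 locus per gene. The cut at 20 applied to both lists of the group that holds a locus. A control-only or knockdown-only locus still had no peak of any strength in the other group. For 1 locus per gene, only loci placed in a single gene were thinned, and all other loci were kept. The scripts were tested on simulated lists of 23316 loci and found 4574 of 4574 lost and 3581 of 3581 gained loci. These simulated lists had no peaks missed near the threshold and no genes whose loci moved together. Full recovery was thus fixed by construction and says nothing on accuracy in the real lists. Among random lists of 30 genes without an effect, 2% were called for loss and 2.5% for direction at an unadjusted p under 0.05, and all 10 lists simulated with 3 times the lost share were called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.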

Results

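The series profiled N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, by antibody enrichment and sequencing (MeRIP-seq). The RNA came from the chromatin-associated fraction of A375 cells, an established human melanoma line, after removal of ribosomal RNA. Its title names CENPA, the histone H3 variant of centromeres, and m6A on centromeric RNA. Of the 32 samples in 16 groups, 4 m6A-enriched libraries are described here: 2 from cells with a control hairpin RNA and 2 from cells with a hairpin RNA against METTL3, the catalytic subunit of the main m6A methyltransferase. The input libraries, the libraries with targeted demethylation by dCas13b-FTO, the second knockdown set and the HEK293T libraries are not analysed here. Each library was represented by its list of called peaks. The control lists held 45345 and 47692 peaks and the knockdown lists 44108 and 42969 peaks. The read depth behind the lists is unknown, and nothing in the labels says whether replicates were separate cultures, so the spread between replicates may be technical.

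METTL3, the targeted gene, carried peaks in every library. On the minus strand of chromosome 14 (hg38), its transcript had 4 loci shared by both control lists and 4 shared by both knockdown lists, and 3 of them were in all 4 lists. A locus near the gene end at 21499103 to 21499725 was found in the control lists only, with fold enrichments of 3.75 and 2.69 in replicates 1 and 2. A locus at 21510585 to 21510767, which lies 617 bp inside the gene start, was found in the knockdown lists only, with folds of 4.39 and 4.14. Peak lists do not measure the amount of an RNA, so these values neither show nor exclude that METTL3 RNA fell.

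The question of the comparison is which m6A loci of chromatin-associated RNA depend on METTL3. Knockdown lists were shorter, with a mean of 43539 ± 805 peaks (SD, n = 2) against 46519 ± 1660 in control (SD, n = 2). An exact two-sided permutation test gave p = 0.333, the smallest p that 2 against 2 libraries allow. The covered length was 17.3 Mb ± 0.259 in knockdown and 17.6 Mb ± 0.799 in control (SD, n = 2 each; exact permutation p = 1). The order of the lists turned when only peaks with a fold enrichment of at least 4 were counted: knockdown lists then held 21325 and 20642 peaks and control lists 20629 and 18947. Median folds were higher in the knockdown lists (3.92 and 3.93) than in the control lists (3.84 and 3.65). A common cut can by itself leave the knockdown lists more peaks.

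Lists of the same group resembled each other more than lists of different groups. The base-pair Jaccard index was 0.713 between the control lists and 0.684 between the knockdown lists. The 4 pairs of 1 control and 1 knockdown list gave 0.511 to 0.513. Merging the peaks by strand gave 66409 loci, of which 23691 (35.7%) were in all 4 lists.

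Both groups had many loci that the other lacked. Of the 36660 loci in both control lists, 8299 (22.6%, 95% Wilson interval 22.2% to 23.1%) had no peak in either knockdown list and are called control-only here. Of the 33195 loci in both knockdown lists, 6285 (18.9%, 18.5% to 19.4%) had no peak in either control list and are called knockdown-only. Splitting the same 4 libraries in the other possible ways, with 1 control and 1 knockdown library in each part, gave 507 to 859 loci per part. Control-only loci outnumbered knockdown-only loci 1.32 to 1, but the ratio was 1.04 with all lists limited to the length of the shortest and 0.86 among peaks with a fold of at least 4. Intervals over loci cover counting error only, and each fold is the authors' own value for a peak within its list.

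**Figure D1:**
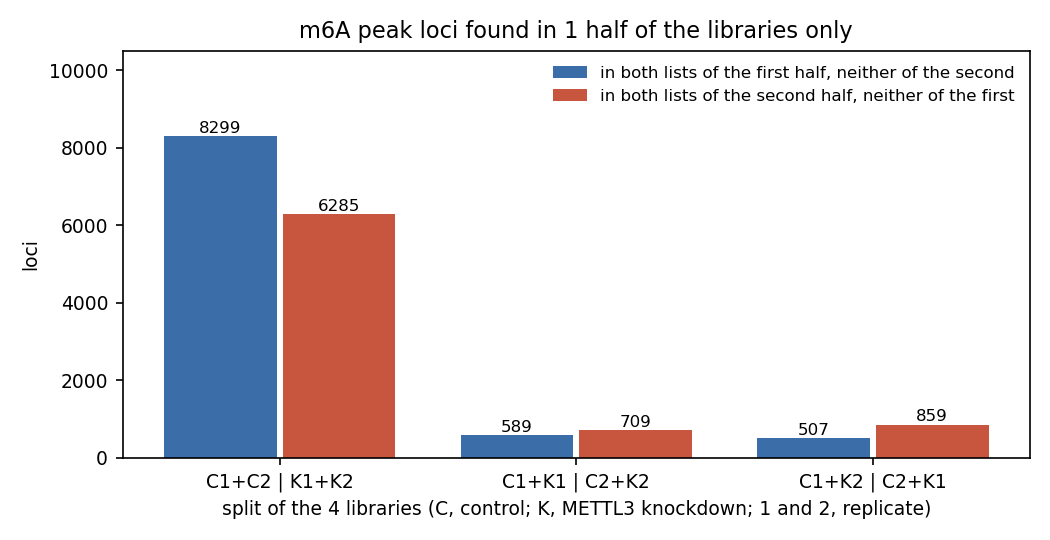
Number of loci (vertical axis) with a peak in both libraries of one part and in neither of the other, for the 3 ways to split the 4 libraries; C is control, K is METTL3 knockdown, and the number is the replicate. The split by group gave 8299 and 6285 loci, against 507 to 859 for the other splits.

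The strongest control-only loci lay in 12 genes of varied function. LRRTM4, which encodes a synaptic adhesion protein, had the highest-ranked locus (chromosome 2, 76807816 to 76808167, inside the gene), with folds of 10.9 and 9.67 in control replicates 1 and 2. LAMA4, a laminin chain, had a locus at 112175390 to 112175583 on chromosome 6 with folds of 11.2 and 8.75. In this gene 11 of the 12 loci of both control lists were control-only. TLN1, encoding the integrin-binding protein talin, lost 5 of 12 loci, and CDH11, a cadherin, 7 of 11. MAP1A, a microtubule-associated protein, had folds of 9.50 and 9.93 at 43522396 to 43522805 on chromosome 15. The splicing-associated gene SRRM2 had a control-only locus 63 bp from its start (chromosome 16, 2752600 to 2752832; folds of 8.91 and 8.29), while 8 of its loci were in all 4 lists. PRRC2B, SLC16A8, AKAP9, ADGRV1 and GON4L completed the named set, together with the pseudogene SEPTIN7P13, which shares sequence with its parent gene and is uncertain for that reason.

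The strongest knockdown-only loci included HSPA6, an inducible heat shock protein gene, with folds of 9.97 and 11.7 in knockdown replicates 1 and 2 at 161525873 to 161526454 on chromosome 1. Both of its knockdown loci were absent from the control lists. The highest-ranked was in RAB20, a small GTPase gene (chromosome 13, 110523501 to 110524264, 576 bp from the gene end; folds of 12.6 and 11.3). MINAR1 had 5 loci in both knockdown lists, all of them knockdown-only. SYBU had 2 of 2, ATP10A 5 of 12, and RALGPS2 3 of 6. PTPRF, a receptor phosphatase gene, had loci of both kinds, with 5 control-only and 3 knockdown-only. ABTB3 had 1 and 3.

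Among the loci shared by all 4 lists, 6 were named by the highest value of their lowest fold percentile. Being shared was thus part of their selection. SLC25A53 reached 18.2 and 16.5 in the control lists and 17.3 and 14.6 in the knockdown lists (X chromosome, 104129972 to 104131337). TAF3, a subunit of the general transcription factor TFIID, had folds of 17.0, 15.7, 15.7 and 14.4 in the same order. CLSPN, ARHGAP18, CCAR1 and OGDH also ranked above the 99.8th percentile of folds in each list.

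Within each library, loci found in 1 group only were weaker than shared ones. The median fold of control-only loci was 3.56 in control replicate 1, against 4.21 for loci that also had a knockdown peak, and 3.45 against 4.03 in control replicate 2. Knockdown-only loci had medians of 3.71 and 3.73, against 4.40 and 4.35. Each of the 4 two-sided permutation tests over loci (100000 resamples) gave p = 1e-05, the smallest they can give. Loci are not replicates, and these tests describe the 4 libraries. Their direction was largely fixed beforehand, because weak peaks near the threshold are the most easily missing from another list. They therefore say nothing on METTL3.

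Whole genes lost or gained their loci. Of 8625 genes with a locus in both control lists, 809 (9.38%) kept none of these in either knockdown list. Of 8605 genes with a locus in both knockdown lists, 837 (9.73%) had none of these in either control list. The following genes were chosen after their values were seen. FN1, encoding fibronectin, had 12 control-only loci and no peak in either knockdown list. HSPH1, a heat shock protein gene, had 9 control-only loci, SH3TC2 7 and KCNAB1 6, with no locus kept. The cadherin gene CDH4 had 10 knockdown-only loci and PDE7B 7, with no locus in both control lists. Other genes had many knockdown-only and no control-only loci, beside 6 to 19 loci in all 4 lists: SLC35F3 with 46, CDH13 with 30, KIRREL3 with 27, RUNX1 with 19 and the lncRNA EPIC1 with 16. TNC, encoding the matrix protein tenascin-C, had 17 control-only and 0 knockdown-only loci and kept 9 loci in all 4 lists. No test is given for single genes, because loci of a gene moved together.

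**Figure D2:**
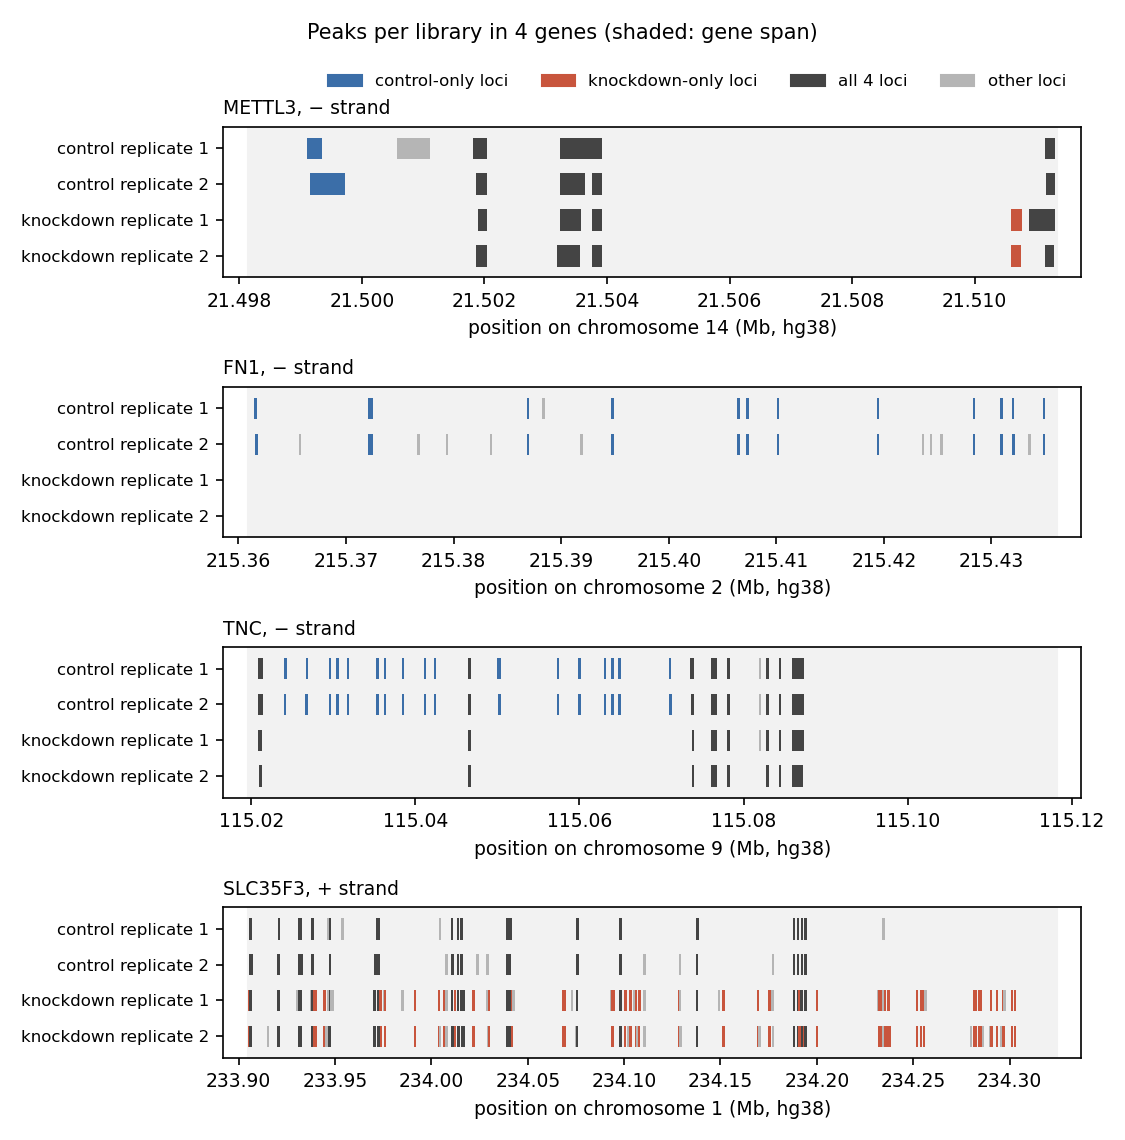
Peaks of each library (rows) along METTL3, FN1, TNC and SLC35F3 (horizontal axis, position in Mb; shading, the gene span), coloured by whether their locus was control-only, knockdown-only, in all 4 lists or of another pattern; narrow peaks are drawn at a minimum width. FN1 had peaks in the control libraries alone, TNC had 17 control-only loci beside 9 shared ones, and SLC35F3 had 46 knockdown-only loci beside 19 shared ones.

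Gene groups fixed before the data were examined mostly did not differ by test from other genes in their shares of lost and gained genes. A gene counts as lost only if all its loci in both control lists are control-only, which genes with many loci can hardly meet. These shares therefore depend on loci per gene, which were not matched. The 8 genes of the m6A writer complex had 40 such loci, and the 28 measured ribosomal protein genes had 44. No list differed in its share of lost genes among the 13 tested (two-sided Fisher's exact tests over genes, Benjamini-Hochberg adjusted). At an unadjusted p under 0.05 there was 1, the ribosomal proteins, with 6 of 28 lost (21.4% against 9.34% of other genes; Fisher's exact p = 0.042, adjusted p = 0.546). RPL31, RPL11, RPL34 and RPS16 were among these. One group differed in its share of gained genes, the replication-dependent histones, whose mRNAs end in a stem-loop instead of a poly(A) tail.

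Of 32 histone genes with a locus in both knockdown lists, 13 (40.6%, Wilson interval 25.5% to 57.7%) had none of these loci in either control list, against 9.61% of other genes (adjusted p = 4.96e-05, Fisher's exact test over 8605 genes). Most of these histone genes had only 1 such locus, and a gene with few loci more easily has all of them knockdown-only. Loci per gene were not matched, so this contrast is partly set by their number. H2AC14 gained 2 loci, and H2AC11, H2BC12, H3C10 and H4C12 gained 1 each. H4C5 and H4C16 kept their locus in all 4 lists, and H3C6 and H2BC18 each had a control-only locus. Each knockdown list held peaks at 44 histone gene loci and each control list at 21. Histone genes are near-identical copies in clusters, so the assignment of peaks to single copies is uncertain. The copies are also not independent, so p-values over these genes are too small. Compared within 5 classes of peak strength, the odds ratio was 2.88 (95% interval 1.39 to 5.96) instead of 6.43 (3.17 to 13.1), with an adjusted p of 0.0803 in an exact stratified test. The planned chi-square approximation kept the call (adjusted p = 0.0407); the exact test replaced it after that result was seen.

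A further test, added after the data were seen, asked whether the moved loci of a list lay on one side. Of the control-only and knockdown-only loci together, 56.9% were control-only. Among the histone genes 2 were control-only and 18 knockdown-only (adjusted p = 0.0052, permutation of genes with as many moved loci). The draws take genes as independent, which clustered histone copies are not, so this p is too small. In the DNA damage response list, 26 were control-only and 3 knockdown-only (p = 0.009, adjusted p = 0.0585, permutation test). This list included TP53BP1 with 5 and 0, ATR with 4 and 1, and WRN, a RecQ helicase gene, with 3 and 0. The nuclear and host lncRNAs had 4 and 15, with PVT1 holding 9 of the 15 and TUG1 2 (adjusted p = 0.316, permutation test). Among the immediate-early regulators the numbers were 2 and 8, with MYC at 0 and 2 (adjusted p = 0.325, permutation test). Histone genes no longer passed with a fold of at least 4 (33.3% control-only) or with a −log10 q of at least 20 (10%; adjusted p = 0.173, permutation test), and the damage response list passed only with lists of equal length. Its control-only share of 89.7% fell to 68.6% without knockdown replicate 1, 72.1% without knockdown replicate 2, 74.4% with reciprocal overlap and 60% with a fold of at least 4. Leaving out a knockdown list raises knockdown-only loci in all genes, so the falls without a knockdown list are partly by construction.

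**Figure D3:**
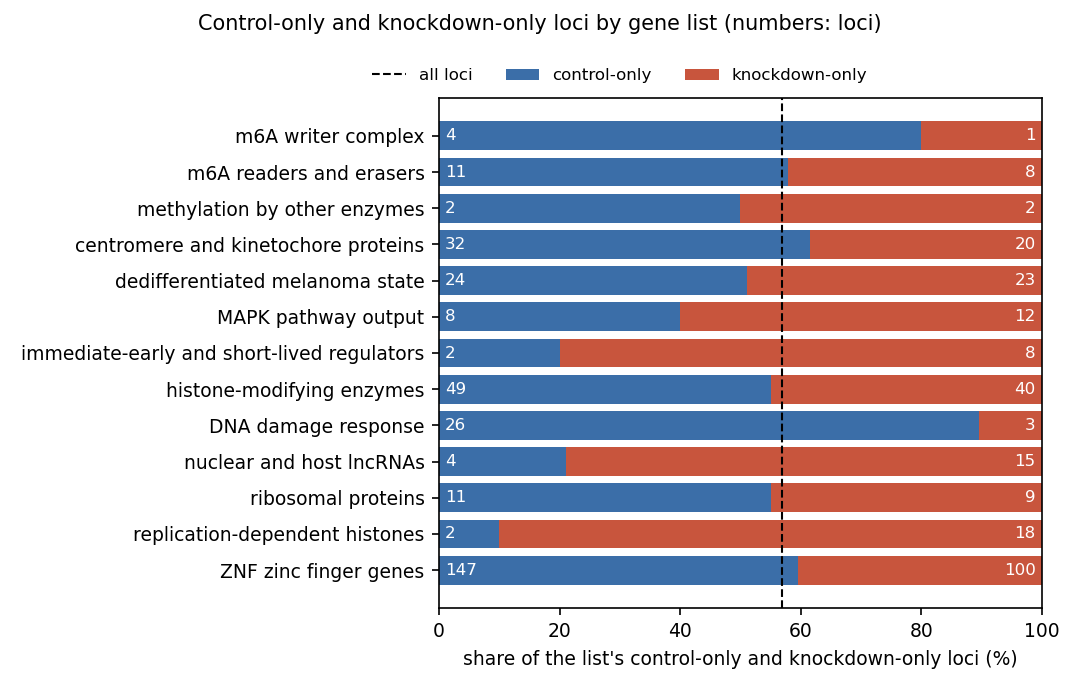
Share of control-only and knockdown-only loci (horizontal axis, %) among both kinds together for each gene list with at least 5 measured genes; white numbers are loci, and the dashed line is the share over all loci, 56.9%. The histone list had 2 control-only and 18 knockdown-only loci, and the DNA damage response list 26 and 3.

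Centromere and kinetochore proteins, the group nearest to the series' subject, did not stand apart in the tests over genes. These tests did not match the number of loci per gene. Of 28 measured members 2 were lost, CENPQ and CENPK, and of 29 members 3 were gained, among them CENPA with a single knockdown-only locus (adjusted p = 1 and 0.985, Fisher's exact tests over genes). The list held 32 control-only and 20 knockdown-only loci. HJURP, the chaperone that loads CENPA, had 4 control-only loci and 5 in all 4 lists, and SGO2 had 4 and 2. MAD1L1, a spindle checkpoint gene, had 8 knockdown-only loci and 5 in all 4 lists. CENPE kept 17 loci and INCENP 11 in all 4 lists.

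The remaining groups gave these values, none past the test. Low shares of lost genes in lists with many loci per gene follow in part from the definition of a lost gene. Of the m6A writer complex 0 of 8 genes were lost; ZC3H13 kept 11 of its 14 control loci in all 4 lists. Of m6A readers and erasers 0 of 12 were lost, and FMR1 had 3 knockdown-only loci. Genes of methylation by other enzymes lost 0 of 7, with METTL16 keeping 7 loci. Histone-modifying enzymes lost 3 of 41, which were KMT5C, HDAC1 and HDAC3, while KDM5A had 8 control-only loci and EHMT1 8 knockdown-only loci. The list of MAPK pathway output lost 1 of 18, the transcription factor ETV1. Genes of the dedifferentiated melanoma state lost 0 of 13, with 24 control-only and 23 knockdown-only loci, TNC alone holding 17 of the 24. Zinc finger (ZNF) genes lost 22 of 316 and gained 18 of 311 (5.79% against 9.87%; adjusted p = 0.0948, Fisher's exact test over genes). The odds ratio of gain passed the threshold at 0.478 without control replicate 1 and 0.55 without control replicate 2. With a fold of at least 4, ZNF genes passed for both gain and loss, at odds ratios of 0.48 and 0.479. Loss turned to 1.2 with reciprocal overlap and to 1.02 within classes of peak strength, where gain was 0.866 and 0.759, none of these past the threshold. In the melanocyte lineage 0 of 4 were lost, which was too few for a test. Markers of other cell types had a locus in 1 of 10 keratinocyte, 2 of 10 fibroblast and 1 of 10 leukocyte genes, and the melanocyte lineage list in 5 of 17. Peak lists do not measure the amount of an RNA, so these counts do not tell cell types apart.

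Position within the gene was related to loss. Gene ends here include every locus of genes shorter than 2000 bp, such as the histone gene H4C5. In genes without an inferred strand, start and end follow the strand of the locus. Loci at gene starts were lost least, 231 of 1511 (15.3%, Wilson interval 13.6% to 17.2%), followed by gene ends with 592 of 3646 (16.2%, 15.1% to 17.5%). In gene interiors, which held 67.9% of the control loci, 23.3% were lost. Loci outside genes and on the opposite strand of a gene were lost most, 28.9% and 29%. Each of these 5 classes differed from all other loci (two-sided Fisher's exact tests over loci; adjusted p from 5.21e-23 to 0.00833), and loci in more than 1 gene did not (21.7%, adjusted p = 0.171). The gained shares were 17.4% at gene starts, 18.4% in interiors, 19.2% at gene ends, 22.2% outside genes and 31.3% on the opposite strand, of which interiors, outside genes and the opposite strand passed. Some of these calls ended under other settings. Loss on the opposite strand did not pass with a fold of at least 4 (odds ratio 1.26), without knockdown replicate 1 (adjusted p = 0.282, Fisher's exact test) or with a −log10 q of at least 20 (odds ratio 1.37), and loss in interiors did not with reciprocal overlap (1.02) or a gene end of 1000 bp (1.06). Gain in interiors did not pass without knockdown replicate 1 (0.961), without knockdown replicate 2 (0.967) or with a −log10 q of at least 20 (0.925), and gain outside genes did not with a fold of at least 4 (adjusted p = 0.0632, Fisher's exact test). Loci of a gene can move together, so Fisher's p over loci is too small. With 1 locus per gene, drawn at random as a check added after the data were seen, interiors passed neither for loss (odds ratio 1.05) nor for gain (0.944), loci outside genes did not pass for gain (1.06), and gene ends did (1.21). Gain at gene ends also passed with a fold of at least 4 (adjusted p = 0.0228, Fisher's exact test), and in the other direction without knockdown replicate 2 (odds ratio 0.905). Gain at gene starts passed with lists of equal length (0.862), within classes of peak strength (0.853) and without knockdown replicate 1 (0.88). Loss in more than 1 gene passed without knockdown replicate 2 (0.903), with a −log10 q of at least 20 (0.868) and with 1 locus per gene (0.86). Gain in more than 1 gene also passed with 1 locus per gene, at an odds ratio below 1. In that setting only loci placed in a single gene were thinned. Loci in more than 1 gene, outside genes or on the opposite strand were all kept, and only the loci compared with them changed. Calls of these classes there are therefore no check with dependence removed.

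**Figure D4:**
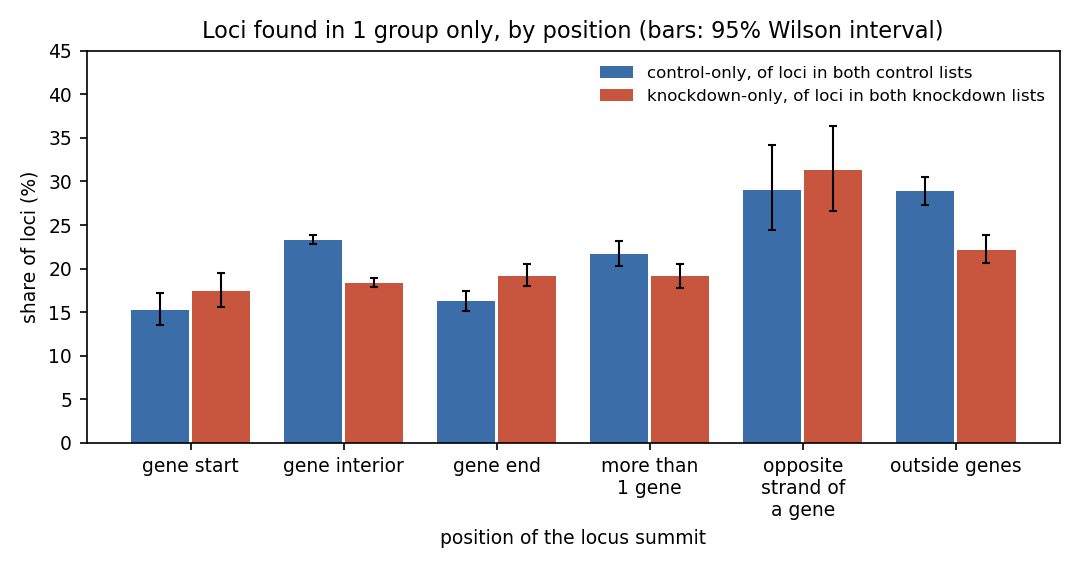
Share of loci found in 1 group only (vertical axis, %) by the position of the locus summit; blue bars are control-only loci among those in both control lists, red bars knockdown-only loci among those in both knockdown lists, and error bars are 95% Wilson intervals over loci. Control-only shares were 15.3% at gene starts and 28.9% outside genes.

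Centromeric RNA was approached through 27 intervals of at least 2 Mb without an annotated gene, 173.5 Mb in all. They stand in for centromeres, were not checked against centromere annotation and are not limited to centromeres. How much of their length reads can align to was not checked, so a low count of peaks does not show that m6A is scarce there. Peaks there were few, with a mean of 16.5 ± 0.707 in knockdown and 6.5 ± 0.707 in control (SD, n = 2 each; exact permutation p = 0.333, the smallest possible). Of 12 loci in both knockdown lists 9 were knockdown-only (75%, against 18.9% of other loci; adjusted p = 7.83e-05, Fisher's exact test over loci). They lay in 1 interval each of chromosomes 1, 4, 15, 17 and 19, with 3 each on chromosomes 15 and 19, so they are not independent and this p is too small. Examples are loci at 26728483 to 26728678 on chromosome 17 (folds of 7.61 and 5.58) and at 27649157 to 27649630 on chromosome 19 (4.28 and 3.93). Of 6 loci in both control lists 2 were control-only, 1 of them at 49623148 to 49623387 on chromosome 4 (6.79 and 5.89). Reads from repeats align to many places, and at a fold of at least 4 there was 1 knockdown-only and 1 control-only locus. There were 3 and 1 with a −log10 q of at least 20, and 14 and 3 without knockdown replicate 2.

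Loci within 5 Mb of these intervals were lost less often than others, 517 of 2667 (19.4% against 22.9%; adjusted p = 7.83e-05, Fisher's exact test over loci), and also gained less often, 17.3% against 19.1% (adjusted p = 0.0349, Fisher's exact test over loci). Loci of a gene can move together, so both p-values are too small. The gained share was not rerun under other settings. The strongest loci near the intervals were shared by all 4 lists: TMEM11, MKRN3, SPAG5 and the uncharacterized genes LOC124902169 and LOC124900706. SPAG5, a mitotic spindle gene, also had 3 control-only loci. On the mitochondrial genome, whose RNA lies outside chromatin, there were 10.5 ± 0.707 peaks in control and 8 ± 1.41 in knockdown (SD, n = 2 each; exact permutation p = 0.333).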

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

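The checks with a gene end of 1000 bp, with a −log10 q of at least 20 and with 1 locus per gene were chosen after the data were seen. Of the alternatives to the main results, 83 were classed as unchanged, 11 as moved and 1 as reversed. For counts, unchanged means a similar size, and for peaks per library a change within their SD. For a test it means the same direction and the same side of the threshold. A moved count can keep its direction. The fold threshold changed several results. At a fold of at least 4 the difference in peaks per library (control minus knockdown) went from 2980 to -1195.5. Control-only loci fell to 3465, knockdown-only loci to 4029 and their ratio to 0.86. In this setting 1 list (ZNF genes) passed for loss at an odds ratio of 0.479. That odds ratio was 1.2 with reciprocal overlap and 1.02 within classes of peak strength, above instead of below 1 and not past the threshold. The cause was not tested. Within classes of peak strength, 0 lists passed for gain by the exact test (1, the histones, by the chi-square approximation; adjusted p of 0.0803 and 0.0407). With a −log10 q of at least 20 there were 3805 control-only and 2522 knockdown-only loci, fewer because loci below that strength are left out, and the direction of the histone list did not pass (adjusted p = 0.173, permutation test). Leaving out a library asks for 1 list instead of 2 and so raises the counts: control-only loci ranged from 10492 to 13799 (13799 without control replicate 1), knockdown-only loci from 7600 to 11218 (10645 without knockdown replicate 1 and 11218 without knockdown replicate 2), and the lists called for gain from 1 to 2, the second being ZNF genes without control replicate 1 or 2. The ratio of control-only to knockdown-only loci then ranged from 0.935 to 1.82 and the odds ratio of gain at gene ends from 0.905 to 1.05, both lowest and below 1 without knockdown replicate 2. With 1 locus per gene the odds ratio of gain for loci in more than 1 gene was 0.837 and passed, against 1.01 without a call in the main run. Loci in more than 1 gene were not thinned themselves, only those compared with them, so this call says nothing on dependence between loci. The 12 control-only, 8 knockdown-only and 6 shared named top loci kept their class in every alternative run on them, which says little, because they were picked for high folds and leaving out a library cannot change these classes. The odds ratio of loss near gene-free intervals stayed between 0.77 and 0.831. Replicate numbers did not pair the libraries: across loci in all 4 lists, the correlation of the control with the knockdown difference between replicates was 0.0107. With the replicate number as a block, the mean difference in peaks was 2980 (1237 and 4723; exact sign-flip p = 0.5, the smallest possible) and control-only loci were 8299 by construction. The motif and repeat alternatives were not run, and fold of at least 4 left too few histone genes for the gained share.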

Other observations

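The following biology was chosen after its values were seen. Beside FN1, TNC and LAMA4, control-only and no knockdown-only loci were found in NRP1 (12) and SEMA3A (11), a receptor and its secreted ligand in axon guidance, and in CDCP1 (12), where 1, 8 and 5 further loci were in all 4 lists. ZBTB20, MTAP and CEP350 had 12 control-only loci each. Knockdown-only and no control-only loci were found in the guidance receptor ROBO2 (7, beside 10 in all 4 lists), in FYN (11), a Src-family kinase gene, and in the amino acid transporter SLC7A5 (7, beside 1 in all 4 lists). FLG, encoding the epidermal protein filaggrin, had 6 knockdown-only loci and none in both control lists.

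Among 3 patterns weighed, the tests of random misses near the threshold and of loci changing on their own were chosen after the result was seen. The first pattern is the excess of control-only over knockdown-only loci, 1.32 to 1. It was 0.86 with a fold of at least 4 and 0.935 without knockdown replicate 2, but neither value decides on a net loss. Leaving out a knockdown list lowers the ratio by construction, because knockdown-only loci then need 1 list, and leaving out a control list raises it. The fold cut was common to all lists, while median folds were higher in knockdown (3.92 and 3.93) than in control lists (3.84 and 3.65). With a −log10 q of at least 20 in the lists that hold a locus, and no peak of any strength in the other group, control-only loci stayed in excess. This cut was also common to all lists and the read depth is unknown, so it does not decide either. Peaks missed by chance in single lists cannot account for the loci found in 1 group only, since control-only loci were 9.66 times the highest count of the other splits. With all lists limited to the length of the shortest, the ratio was 1.04. Equal lengths bring both counts towards balance whatever the cause, and a net loss of loci would itself shorten the knockdown lists, so this test decides nothing. Longer control lists and a net loss of m6A loci after METTL3 knockdown cannot be told apart here. A biological effect of METTL3 on single loci stays open and untested.

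The second pattern is that loci of a gene moved together. Of 687 genes with at least 4 moved loci, the moved loci were all control-only in 245 and all knockdown-only in 140, 56% together against a median of 8.01% (95% range 6.11% to 10%) when the kinds were shuffled over loci, which argues against each locus changing on its own. Segments of chromosomes that differ between the cell populations would give neighbouring genes one direction. Of 5488 neighbouring pairs 52.8% shared it, against a median of 50.5% in shuffles (95% range 49.2% to 51.9%); this excess of 2.28 percentage points is above the shuffles but under the 5 required, so a small part played by such segments stays open. Within 1 Mb, TNC shared its direction with 5 of 6 genes with moved loci and KIRREL3 with 0 of 5. A candidate explanation that stays open is a change in the amount of RNA of these genes on chromatin, which was not tested, because the input libraries are not analysed here. It would have to leave part of the peaks of a gene in place, since SLC35F3, CDH13 and TNC kept 19, 18 and 9 loci in all 4 lists. Of genes with at least 6 loci in both lists of a group, 4 lost and 6 gained all of them.

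The third pattern is the set of histone genes with peaks in the knockdown lists alone. Leaving out either knockdown list gave an adjusted p of at most 0.00255 (Fisher's exact test), but gained loci have a peak in both knockdown lists by definition, so this outcome was largely fixed and tests nothing. Weak peaks crossing the threshold may account for part of it. Within 5 classes of the knockdown fold percentile the odds ratio was 2.88 instead of 6.43. The adjusted p was 0.0803 in an exact test and 0.0407 by the chi-square approximation. The gained share thus cannot be told apart from peak strength at these numbers of genes. The number of loci per gene was not matched in either comparison and may account for part of the odds ratios. Weakness alone would make histone peaks go missing from either group. Histone gene peaks had median fold percentiles of 25.6 and 19.9 in the control lists and 30.1 and 21 in the knockdown lists. Each knockdown list nevertheless held 44 of them and each control list 21, and 18 moved loci were knockdown-only against 2 control-only. These values argue against weakness alone for the direction in this set, though the copies are not independent. A higher amount of histone RNA on chromatin, for example from another share of cells in S phase, stays open as an untested hypothesis.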
